A study of Homo sapiens with 6 samples.

How the data were processed

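Gene expression was measured by RNA sequencing in 6 libraries of HAP1 cells, 3 wildtype and 3 DEGS1 knockout. Per the labels' protocols, cells were passaged 3 times a week, grown in medium with 5% serum and collected 24 h after passage, RNA was extracted with an organic reagent, and 1 ug of total RNA went into a stranded total RNA library kit sequenced as single reads of 75 nt. The values are whole-number counts of reads per gene symbol, not normalized, as the authors deposited them. Per the submitters' processing notes, bcl2fastq 2.20 and the genome build hg19 were used. The aligner, the counter, the gene annotation and the strand setting of the counting are not given in the sources used here, so overlapping genes, antisense genes and genes with near-identical copies could have been split or merged by the counting. The annotation held in hand is of another build, so no coordinates are given.

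The table holds 35238 symbols, 9519 of them with no count in any library. The RefSeq gene table of GRCh38.p14 placed 27330 symbols (77.6%) on a chromosome and was used only for names, chromosome membership and the order of neighbours. Of 1197 genes in 37 lists, 1195 were matched, 80 through an older symbol.

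Genes were tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by the trimmed mean of M values, genes were kept by edgeR's expression filter with genotype as the group, and a quasi-likelihood F test with robust dispersion was run on genotype alone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error is the absolute log2 fold change over the square root of F, and CPM values use the scaled library sizes. The common dispersion gave a biological coefficient of variation of 16.4%. Lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Fry tests whether the genes of a list move on balance one way, or change in either direction, and does not set a list against other genes. The correlation between the members of a list left after genotype was also set against 1000 random lists of the same size, drawn within 10 classes of mean expression.

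The design, the lists, the rule for named genes and the first group of alternatives below were set before the data were examined. The rule names DEGS1, DEGS2 and FADS3; the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap and whose higher group had a mean of at least 5 CPM; the 5 smallest p-values; and up to 4 called members of each list, or the member with the smallest p. This gave 99 genes. Some of them are not reported here. Others are named in the closing section and were chosen after their values were seen.

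Medians per chromosome were taken over genes with a mean log2 CPM above 3, after the median of all such genes was subtracted in each library. Chromosome 16 was taken in 2 parts at its widest stretch without a tested gene, and this split was chosen after seeing the data. Transcript length and GC content came from the longest transcript of each gene in GENCODE release 29 and were known for 94.1% of tested genes. A spline with 4 degrees of freedom in each gave each library's trend.

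The pipeline was tested on simulated data with the means and library sizes of this comparison. Of genes changed 1.5-fold 19.4% of 67 were recovered, of those changed 2-fold 64.6% of 65, and of those changed 4-fold 91.9% of 62, with 9 false calls among 16668 tested. A simulated raised list was called, 0 of 37 unchanged lists were called by camera on these independently drawn genes, and a simulated log2 shift of -0.3 on chromosome 13 was fitted as -0.28.

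Totals per library were 24170525, 28988522 and 17322756 counts in wildtype and 19389644, 27604956 and 27659835 in the knockout. A count of 3, the floor used here, corresponds to 0.109 to 0.161 CPM. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The labels do not say whether the replicates were separate cultures or how many knockout clones were used, so p-values measure the spread between these libraries, which may be technical. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of 11.7 to 48.2.

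The first group of alternatives was DESeq2 1.42.0 size factors, upper-quartile scaling, library size only, the DESeq2 Wald test, limma voom, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, the 10 most abundant genes left out, and a threshold of 0.01. Removal of the length and GC trend and removal of chromosome medians were added after seeing the data.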

Results

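RNA was sequenced from HAP1, an established human cell line that is near-haploid, meaning that most of its chromosomes are present in a single copy. There were 3 libraries from wildtype cells and 3 from cells in which DEGS1 had been knocked out. DEGS1 encodes the desaturase that converts dihydroceramide to ceramide, the last step of ceramide synthesis. The question the series states is what the loss of this enzyme does to the cell, and the design gives 1 comparison, knockout against wildtype. Total counts ran from 17322756 to 28988522 per library in wildtype and from 19389644 to 27659835 in the knockout. Log2 fold changes are given as knockout over wildtype with their standard error (SE), from 3 libraries per genotype, and every adjusted p of a gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

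DEGS1 itself was low in each knockout library. It stood at 105, 123 and 95.5 CPM (counts scaled to a common library size) in the 3 wildtype libraries and at 9.49, 6.88 and 10.4 CPM in the 3 knockout libraries, so that 8.3% of the wildtype level remained. The log2 fold change was -3.59 (SE 0.17, edgeR adjusted p = 3.07e-07). Its relatives did not pass the test. DEGS2, a desaturase that also hydroxylates dihydroceramide, had a log2 fold change of -0.58 (SE 0.48, edgeR adjusted p = 0.587) at under 1 CPM, and FADS3, a desaturase of the sphingoid base, had one of 0.43 (SE 0.22, edgeR adjusted p = 0.354), so smaller changes in either are not ruled out. None of the 12 tested genes listed as neighbours of DEGS1 on its chromosome changed in edgeR's test, although 3 had an unadjusted p under 0.05 and 1 fell adjusted over the list alone, and the nearest to the threshold was DNAH14 with a log2 fold change of -0.37 (SE 0.10, edgeR adjusted p = 0.0556). DNAH14 passed in 4 of 17 other settings, among them the fit without wildtype replicate 2 (0.00818).

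Of 16954 genes tested, 756 changed, 256 of them higher and 500 lower in the knockout. An unadjusted p under 0.05 in edgeR's test was reached by 2799 of the 16954, the share against which such counts within a list are to be read. The decreases were also the larger changes. Over 2-fold, 111 genes rose and 311 fell, and over 8-fold 10 rose and 79 fell. In each of the 756 changed genes the 3 knockout libraries lay on one side of all 3 wildtype libraries, as they did in 20.8% of all tested genes against 10% by chance. The counts depended on single libraries: 3825 genes changed without wildtype replicate 2, 441 without wildtype replicate 1, 424 without knockout replicate 1 and 380 without knockout replicate 3. With each library's trend on transcript length and GC content removed, a setting chosen after seeing the data, the split was 397 higher and 455 lower, or 46.6% higher against 33.9%.

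**Figure D1:**
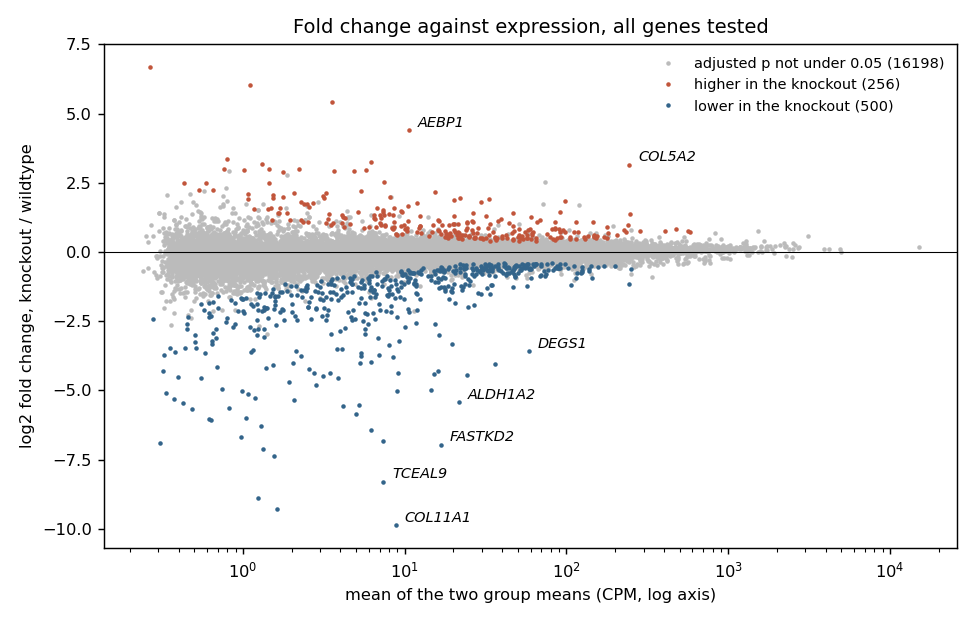
Log2 fold change of every tested gene (vertical axis, knockout over wildtype) against its mean expression (horizontal axis, CPM on a log axis), with genes past an adjusted p of 0.05 in colour. Red points are the 256 genes higher and blue points the 500 genes lower in the knockout, and the decreases reach farther from 0 than the increases.

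The 5 genes with the smallest p-values all fell. ALDH1A2, an enzyme that makes retinoic acid, fell from 42.5 ± 0.723 to 0.983 ± 0.07 CPM (SD, n = 3 each), a log2 fold change of -5.42 (SE 0.15, edgeR adjusted p = 5.89e-09). CWF19L1 fell from 67.8 to 4.14 CPM, CTDSPL from 46.3 to 2.14 CPM, and FASTKD2, a mitochondrial RNA-binding protein, from 33.1 to 0.258 CPM. Also among the 5 smallest p-values was MB21D1, the symbol in the table for the cytosolic DNA sensor cGAS, which fell from 29 ± 1.9 to 1.37 ± 0.0991 CPM (log2 fold change -4.40, SE 0.16, edgeR adjusted p = 4.53e-08).

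The largest decreases included a second DNA sensor, IFI16, with a log2 fold change of -6.44 (SE 0.30). The vesicular nucleotide transporter SLC17A9 had one of -6.81 (SE 0.39), the GABA receptor subunit GABRA5 -5.85 (SE 0.39), the microfibril protein MFAP2 -5.57 (SE 0.53) and the zinc finger gene ZNF676 -5.53 (SE 0.39). PSMB8, a subunit of the immunoproteasome, stood at -5.04 (SE 0.31), the enamel matrix gene AMBN at -4.99 (SE 0.51) and the glycosyltransferase GALNT14 at -4.79 (SE 0.35). COL11A1, a fibrillar collagen, had 1336 counts over the wildtype libraries and 1 over the knockout libraries, a ratio of 1370 after scaling (95% exact interval 246 to 54300, counting error only). TCEAL9 had 1006 against 3 counts, a ratio of 345 (interval 118 to 1680). The call of COL11A1 was lost without knockout replicate 1 (edgeR adjusted p = 0.0845).

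Among the largest increases, COL5A2, another fibrillar collagen, rose from 49.5 ± 10.7 to 438 ± 97.4 CPM (log2 fold change 3.14, SE 0.21, edgeR adjusted p = 6.07e-06). AEBP1, a collagen-binding secreted protein, rose from 0.997 to 20.2 CPM (log2 fold change 4.39, SE 0.29), and ANGPTL2 from 1.19 to 11.2 CPM (3.27, SE 0.30). The transcriptional cofactor EYA2 rose by 2.94 (SE 0.26), the presynaptic scaffold RIMS1 by 2.93 (SE 0.36), and the phosphodiesterases PDE3A and PDE4B by 2.52 (SE 0.21) and 2.02 (SE 0.34). GPR19 (2.21, SE 0.21), ATRNL1 (2.17, SE 0.22) and SLC38A11 (2.15, SE 0.36) rose as well. KRT18P61 had the largest increase of the genes named (5.42, SE 0.36), but it is a keratin pseudogene whose reads could be shared with near-identical copies, so its value is uncertain. RAB34 passed narrowly (2.95, SE 0.63, edgeR adjusted p = 0.0469) and lost its call in 9 of 17 other settings, among them each fit that left out 1 library except the one without knockout replicate 2.

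**Figure D2:**
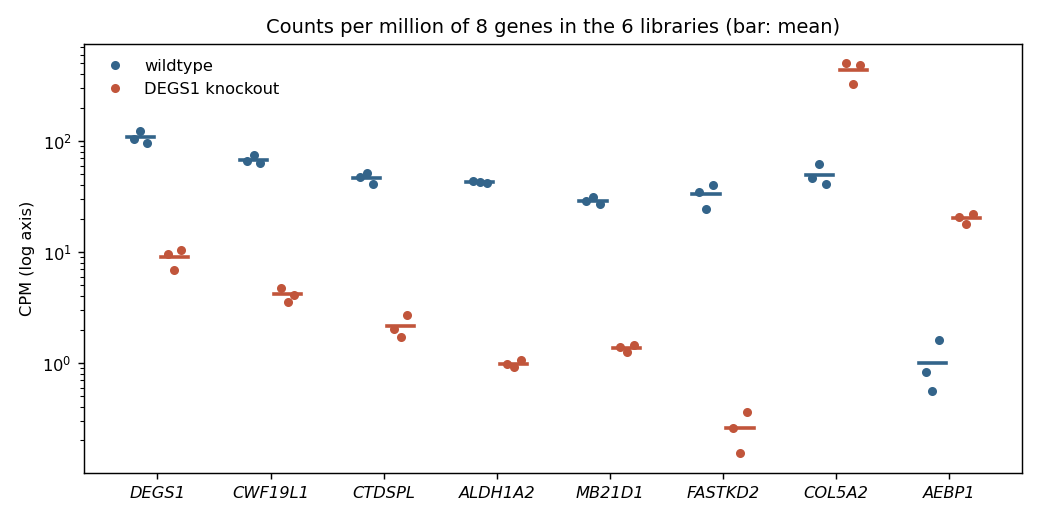
CPM (vertical axis, log scale) of 8 genes in the 3 wildtype libraries (blue) and the 3 knockout libraries (red), with bars at the group means. DEGS1 and 5 genes with strong decreases lie apart from wildtype in each library, and COL5A2 and AEBP1 are the reverse, with COL5A2 at 438 CPM in the knockout against 49.5 CPM.

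Of 29 tested genes of sphingolipid synthesis, 1 fell and 28 did not pass, and adjusted over the list alone 1 rose and 1 fell. The gene that fell over all genes was SPTLC2, a subunit of the serine palmitoyltransferase that starts the pathway, from 155 ± 8.45 to 95.4 ± 7.2 CPM (log2 fold change -0.70, SE 0.11, edgeR adjusted p = 0.00337). SPTLC2 lies on chromosome 14, whose genes were lower as a whole, and with chromosome medians removed its log2 fold change was -0.54 (edgeR adjusted p = 0.00733). Of 38 genes of sphingolipid breakdown and signalling, SPHK1, the kinase that makes sphingosine 1-phosphate, fell by 1.66 (SE 0.23, edgeR adjusted p = 0.00147) and was the only one, also when adjusted over the list alone. Among 17 genes of glycosphingolipid synthesis 2 fell, A4GALT, the synthase of globotriaosylceramide, 2.83-fold (edgeR adjusted p = 0.0029) and the sialyltransferase ST3GAL1 with a log2 fold change of -0.57 (SE 0.14), the latter call lost in 7 of 17 other settings. These were 4 with all libraries (edgeR adjusted p of ST3GAL1 up to 0.0898) and the fits without wildtype replicate 1 (0.185) and without knockout replicates 1 (0.153) and 2 (0.117). Adjusted over the list alone, 1 rose and 2 fell. Of 19 genes of membrane domains and lipid flippases, ATP10A and ATP11A fell, with log2 fold changes of -1.36 (SE 0.19) and -0.74 (SE 0.15). Adjusted over the list alone, 2 rose and 2 fell. ATP11A lies on chromosome 13 and lost its call in 5 of 17 other settings, among them chromosome medians removed (edgeR adjusted p = 0.293), library size only (0.0515), without knockout replicate 1 (0.0726) and without knockout replicate 3 (0.112).

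Other lipid genes gave few calls. APOE, the apolipoprotein that carries lipids out of cells, rose from 8.74 ± 0.993 to 31.9 ± 10.1 CPM (log2 fold change 1.87, SE 0.22, edgeR adjusted p = 0.000579). It was among the 2 genes that rose of 12 genes of lipid efflux and its nuclear receptor, a list that camera called up (adjusted p = 0.0405, and adjusted p = 0.862 with an estimated correlation). The list had 7 positive and 5 negative log2 fold changes and was called in 7 of 17 other settings (camera adjusted p up to 0.142). Adjusted over the list alone, 3 rose. In 25 genes of cholesterol synthesis and uptake 1 fell, also adjusted over the list alone. In 30 genes of fatty acid oxidation CD36 fell, also adjusted over the list alone, but it lost its call in 9 of 17 settings (edgeR adjusted p up to 0.248). In 25 genes of fatty acid synthesis none passed edgeR's test, nor adjusted over the list alone, 3 had an unadjusted p under 0.05, and SCD5 had the smallest p (log2 fold change -0.40, SE 0.13, edgeR adjusted p = 0.136, and 0.00711 without wildtype replicate 2).

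Genes of the extracellular matrix and of cell adhesion changed in both directions. Of 39 tested matrix genes, 5 rose and 4 fell, and adjusted over the list alone 8 rose and 6 fell. Besides COL5A2 and COL11A1, the fibrillins FBN1 and FBN2 fell, with log2 fold changes of -1.53 (SE 0.15) and -1.14 (SE 0.14), FBN2 from 333 ± 48 to 151 ± 5.88 CPM. Of 40 adhesion and cytoskeleton genes, 1 rose and 3 fell, among them the integrin subunit ITGA9 (log2 fold change -2.35, SE 0.17) and the hyaluronan receptor CD44 (-3.10, SE 0.39). Adjusted over the list alone, 5 rose and 3 fell.

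Epithelial and blood cell markers were the 2 lists that camera called down. Of 16 epithelial markers, 5 fell and none rose in edgeR's test, where 6 had an unadjusted p under 0.05, and adjusted over the list alone 1 rose and 5 fell. CLDN1, a tight junction protein, had a log2 fold change of -3.50 (SE 0.30), the adhesion molecule EPCAM -3.01 (SE 0.45) and SPINT2 -1.29 (SE 0.18). The list was called down by camera with its preset correlation (adjusted p = 0.000365), and adjusted p = 0.862 with an estimated correlation. Of 16 mesenchymal markers VIM and ZEB1 rose, with calls lost in 3 and 6 of 17 settings, and 1 fell, the transcription factor PRRX1 with a log2 fold change of -4.38 (SE 0.46), with 4 and 2 adjusted over the list alone. Of 18 blood cell markers, TAL1 rose by 1.04 (SE 0.13) and 3 fell, among them HCLS1 (log2 fold change -3.72, SE 0.34) and RUNX1 (-1.43, SE 0.26). Adjusted over the list alone, 2 rose and 5 fell, and camera called the list down (adjusted p = 0.0405, and adjusted p = 0.862 with an estimated correlation). This call was kept in 9 of 17 other settings, and that of the epithelial markers in all 17.

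Neuron markers changed in both directions, with 8 positive and 7 negative log2 fold changes. Of 15 tested, 4 rose and 2 fell, and adjusted over the list alone 6 rose and 2 fell. MAP2, a dendritic microtubule protein, rose from 25.8 ± 7.17 to 68.1 ± 14.4 CPM (log2 fold change 1.41, SE 0.21), NES by 0.81 (SE 0.14) and NEUROG2 by 0.71 (SE 0.14). MAP2 lost its call without wildtype replicate 2 (edgeR adjusted p = 0.0535) and NES without knockout replicate 3 (0.053), and NEUROG2 lost its call in 3 of 17 settings. Camera called the list up (adjusted p = 0.0381, and adjusted p = 0.862 with an estimated correlation). The list was called in 11 of 17 other settings. In 17 genes of myelin and glia OLIG2 and PDGFRA rose and MOBP fell, with 3 and 3 adjusted over the list alone. Without wildtype replicate 1 none of these 3 passed (edgeR adjusted p = 0.173, 0.191 and 0.204), and they lost their calls in 6, 5 and 7 of 17 settings.

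In 28 genes of the TGF-beta, BMP and Notch pathways 3 fell, with BMP7 from 9.96 ± 1.97 to 0.779 ± 0.0202 CPM (log2 fold change -3.66, SE 0.25) and BMP2 at -2.17 (SE 0.22), and adjusted over the list alone 1 rose and 3 fell. The third gene that fell lost its call in 5 of 17 settings (edgeR adjusted p up to 0.171). In 25 genes of WNT signalling 3 rose and 1 fell, WNT10B rising by 1.23 (SE 0.18), with 3 and 4 adjusted over the list alone. WNT10B kept its call in all 17 settings, but without knockout replicate 3 FZD7 (edgeR adjusted p = 0.127) and DKK3 (0.25), which rose, and LEF1 (0.0514), which fell, did not pass. FZD7, DKK3 and LEF1 lost their calls in 6, 9 and 2 of 17 settings. In 38 interferon-response genes 3 rose and 3 fell, with 5 and 5 adjusted over the list alone. Of those that fell, PSMB8 and IFITM1, a membrane protein that restricts viral entry, had log2 fold changes of -5.04 and -4.55 (SE 0.31 and 0.37), and the class I antigen HLA-B fell from 148 ± 38.5 to 65 ± 6.69 CPM. In 20 genes of NF-kB and inflammation the inhibitor NFKBIA fell by 0.69 (SE 0.11), and 3 fell adjusted over the list alone. NFKBIA lies on chromosome 14, whose genes were lower as a whole. With chromosome medians removed its log2 fold change was -0.53 (edgeR adjusted p = 0.0368). In 26 immediate early genes 2 fell, KLF4 with a log2 fold change of -1.58 (SE 0.23) and NR4A2 with one of -1.44 (SE 0.26), and 3 fell adjusted over the list alone. NR4A2 lost its call in 2 of 17 settings.

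In 38 genes of the integrated stress response DDIT3 and VLDLR rose and SLC7A1 fell, and adjusted over the list alone 3 rose and 1 fell. SLC7A1 lies on chromosome 13 and lost its call with chromosome medians removed (log2 fold change -0.46, edgeR adjusted p = 0.214) and without knockout replicate 3 (0.0637), and VLDLR lost its call in 8 of 17 settings. DDIT3, which encodes the stress factor CHOP, rose by 0.68 (SE 0.14), and lost its call without wildtype replicate 1 (edgeR adjusted p = 0.0644) and without knockout replicates 1 (0.0691) and 3 (0.0949). Camera called this list up (adjusted p = 0.0395, and adjusted p = 0.862 with an estimated correlation). That call was kept in 11 of 17 other settings. In 50 genes of lysosome and autophagy CTSF rose by 0.88 (SE 0.15) and GABARAPL1 by 0.74 (SE 0.13), with 3 adjusted over the list alone, and camera called the list up (adjusted p = 0.0405, and adjusted p = 0.862 with an estimated correlation). GABARAPL1 lost its call in 1 of 17 settings, and the lysosome and autophagy list was called in 12 of 17. None of 32 unfolded protein response genes and none of 18 heat shock genes passed edgeR's test, nor adjusted over the list alone, and 3 in each list had an unadjusted p under 0.05. DNAJC3 had the smallest p of the first list (log2 fold change -0.44, SE 0.12, edgeR adjusted p = 0.0739) and HSPB1 of the second (0.45, SE 0.13, edgeR adjusted p = 0.0886). DNAJC3 lies on chromosome 13, whose genes were lower as a whole, and with chromosome medians removed its log2 fold change was -0.12 (edgeR adjusted p = 0.522). DNAJC3 and HSPB1 each passed in 4 of 17 other settings, among them the fit without wildtype replicate 2 (DNAJC3 0.0303, HSPB1 0.00836), upper-quartile scaling for DNAJC3 (0.0238), and the DESeq2 Wald test (0.0376) and the fit without knockout replicate 2 (0.0469) for HSPB1. In 32 genes of the NRF2 response NQO1 fell, with 1 and 2 rising and falling adjusted over the list alone. NQO1 lies on the far side of chromosome 16 and lost its call in 9 of 17 settings, among them chromosome medians removed (log2 fold change -0.28, edgeR adjusted p = 0.424, from -0.55 and 0.0423). In 22 antioxidant enzymes 1 fell, with 1 adjusted over the list alone.

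Replication-dependent histone genes had a positive log2 fold change in 32 of 36, with a median of 0.275 and 21 at an unadjusted p under 0.05, but the 1 that passed, HIST1H2BE, fell by 0.57 (SE 0.13), also adjusted over the list alone. Ribosomal protein genes were positive in 71 of 75, with a median of 0.147, and 0 passed edgeR's test, over all genes or adjusted over the list alone, or had an unadjusted p under 0.05. Of 76 nuclear genes of the respiratory chain NDUFC2 alone rose, by 0.56 (SE 0.11), as it did adjusted over the list alone. Camera called these 3 lists up (adjusted p = 8.36e-05, 0.00407 and 0.0405), each with adjusted p = 0.862 with an estimated correlation. HIST1H2BE and NDUFC2 each lost their call in 4 of 17 settings. The 13 mitochondrial genes gave no call in edgeR's test, over all genes or adjusted over the list alone, and 0 at an unadjusted p under 0.05, and their share of the counts was 0.72 ± 0.0197% in wildtype and 0.645 ± 0.0467% in the knockout (SD, n = 3 each).

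None of 36 genes of the G1 and S phases and none of 35 genes of G2 and mitosis passed edgeR's test, nor adjusted over the list alone, with 4 in each list at an unadjusted p under 0.05. CDC45 had the smallest p of the first (log2 fold change 0.31, SE 0.12, edgeR adjusted p = 0.218) and NDC80 of the second (-0.47, SE 0.13, edgeR adjusted p = 0.0803). NDC80 passed in 6 of 17 other settings, among them the DESeq2 Wald test (0.0379), upper-quartile scaling (0.0364) and the fit without wildtype replicate 2 (0.0301), where CDC45 passed as well (0.00711). Of 33 cell cycle inhibitors and p53 targets CDKN1C rose and PLK2 fell, as many as adjusted over the list alone. Of 31 apoptosis genes BOK fell, with 1 rising and 1 falling adjusted over the list alone, and of 27 mitochondrial dynamics genes PPARGC1A fell, as it did adjusted over the list alone. CDKN1C and BOK lost their calls in 8 of 17 settings, PPARGC1A in 8 of 16, and PLK2 in 1, without knockout replicate 3 (edgeR adjusted p = 0.0675). In 37 genes of glycolysis and hypoxia 2 rose, the glucose transporter SLC2A3 by 0.94 (SE 0.17) and EGLN3 by 0.86 (SE 0.20), with 2 adjusted over the list alone. SLC2A3 lost its call in 1 and EGLN3 in 7 of 17 settings.

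Over the 37 lists, 9 were called by camera, 7 up and 2 down. With an estimated correlation 0 were called, where 1 list had an unadjusted p under 0.05. By fry, 0 were called in one direction, with 8 at an unadjusted p under 0.05, and 27 in either direction. In splits of the 6 libraries that mixed the genotypes, camera with its preset correlation called 1 to 17 lists. Of the 1081 listed genes tested, 74 changed, and 29 lists held at least 1 of them.

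**Figure D3:**
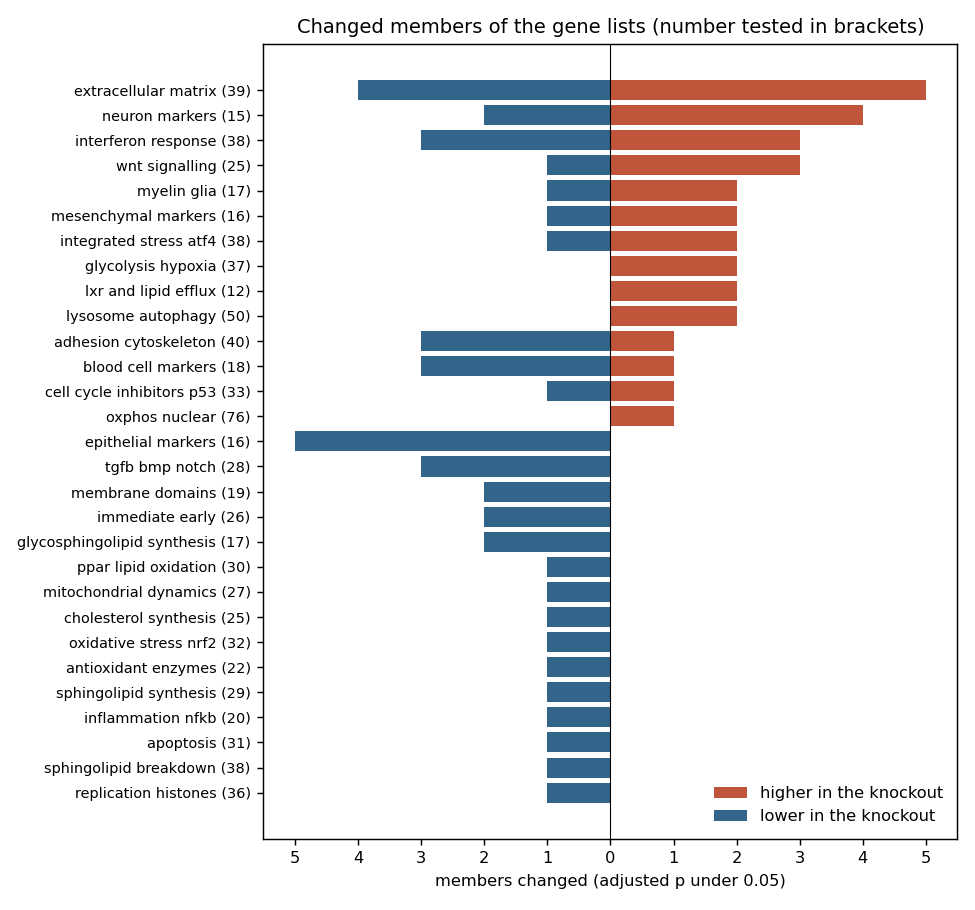
Number of members past an adjusted p of 0.05 in each of the 29 gene lists that held any, with members higher in the knockout to the right (red), members lower to the left (blue), and the number of members tested in brackets. The extracellular matrix list has the most changed members, 5 higher and 4 lower, and the epithelial markers have 5 lower and none higher.

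Genes of chromosome 13, chromosome 14 and part of chromosome 16 were lower as whole groups. The median log2 difference, knockout minus wildtype, was -0.33 over 184 genes of chromosome 13, -0.18 over 349 genes of chromosome 14 and -0.31 over 208 genes of chromosome 16 from SHCBP1 onward. On the other side of the same chromosome, up to ZNF267, it was -0.04 over 255 genes. Per library, the medians of chromosome 13 lay at 0.17 ± 0.05 in wildtype and -0.17 ± 0.05 in the knockout (SD, n = 3 each, log2 deviation from the mean of the 6 libraries). Chromosome membership and order came from a gene table of another assembly, GRCh38.p14. On chromosome 13, 34 of 293 tested genes changed and all 34 were lower, 11.6% against 4.56% elsewhere (Fisher's exact test, two-sided, p = 1.03e-06, adjusted over 24 chromosome parts p = 2.47e-05). The far side of chromosome 16 also held more changed genes, 8.54% (adjusted p = 0.0108), but chromosome 14 did not pass, at 5.03% against 4.67% elsewhere (adjusted p = 0.824). The share was also higher on chromosomes 4 (7.6%, adjusted p = 0.00912), X (7.44%, adjusted p = 0.0108) and 2 (6.26%, adjusted p = 0.0468), whose medians moved by 0.02, -0.002 and 0.04, and lower on chromosomes 17 and 19 and the near side of 16. With chromosome medians removed, a setting chosen after seeing the data, 28 rather than 86 genes on chromosomes 13, 14 and the far side of 16 changed. Elsewhere 562 rather than 670 changed, so calls were also lost outside these 3 parts, and 590 changed in all.

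**Figure D4:**
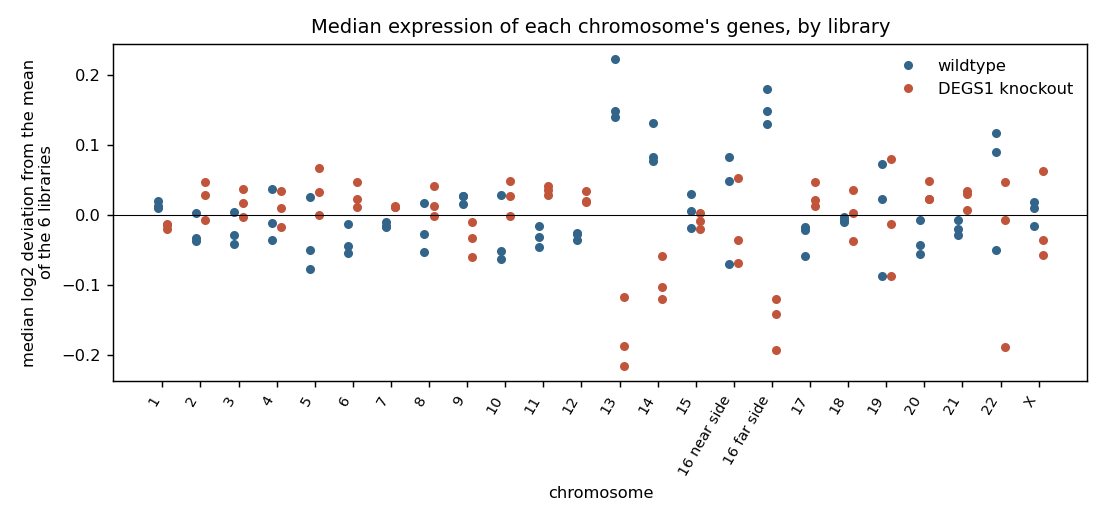
Median log2 deviation of each chromosome's genes from the mean of the 6 libraries (vertical axis) by chromosome (horizontal axis), with 1 point per library, wildtype in blue and knockout in red. On chromosomes 13, 14 and the far side of 16 the 3 knockout libraries lie below all 3 wildtype libraries, by a median of -0.33, -0.18 and -0.31.

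The first principal component of log2 CPM, with 47.9% of the variance, separated the genotypes, with wildtype at -40.7, -3.2 and -49.9 and the knockout at 22.2, 38.6 and 33. Wildtype replicate 2, the wildtype library nearest the knockout there, lay at -50.4 on the second component (26.6% of the variance), where the other wildtype libraries lay at 1.6 and 15.8. Its root mean square log2 distance was 0.561 and 0.659 to the other wildtype libraries and 0.574 to 0.676 to the knockout libraries.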

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

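The length and GC correction and the removal of chromosome medians were chosen after seeing the data. DEGS1 fell past the threshold in each of the 17 settings, with log2 fold changes of -3.72 to -3.43. Of 89 named genes that changed, 51 kept their call in every setting, 38 lost it without at least 1 library and 19 in at least 1 setting with all libraries, and none changed sign. Among named genes not called, NDC80 gained a call in 6 settings, DNAH14, DNAJC3 and HSPB1 in 4 each, and CDC45, RPS14 and SCD5 in 1, without wildtype replicate 2. The count of changed genes was 375 at an adjusted p under 0.01. Genes higher in the knockout numbered 385 with the DESeq2 Wald test and 397 with the length and GC trend removed. Lists called numbered 3 with the stricter filter, 4 with the length and GC trend removed, 0 with an estimated correlation, 0 by fry in one direction and 27 by fry in either direction. The stricter filter tests fewer genes, and the cause of the other shifts was not tested.

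Without 1 library, changed genes ran from 380 (knockout replicate 3) to 3825 (wildtype replicate 2), genes higher from 113 to 1835, genes lower from 267 to 1990, genes over 2-fold from 308 to 899 and lists called from 3 to 10. Of the 756 genes, 747 were again called without wildtype replicate 2 and 371 without knockout replicate 3. Fewer libraries lower the power, but the cause of the rise to 3825 was not tested.

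The labels give both genotypes the same 3 replicate numbers and, with each number, the same label code, without saying what they mark. Deviations from the group means correlated at 0.22, 0.31 and -0.13 between libraries of the same number. Knockout replicate 1 correlated best with wildtype replicate 3 (0.36). Genotype alone was set as the main fit before the data were examined, because the labels state no block. With 3 libraries per genotype these correlations cannot exclude a shared batch. Replicates 2 were the closest libraries across the genotypes (root mean square log2 distance 0.574). They also shared a negative trend on GC content (r across genes -0.21 and -0.19, genes not being independent replicates). This is a hint that the shared label code may mark a batch, which the labels do not state. With the replicate block 1082 genes changed, 390 higher and 692 lower, and 731 of the 756 genes were among them. With the libraries, depth and spread of this comparison, 19.4% of simulated 1.5-fold changes were recovered. The block also gained calls for NDC80 (0.0169), DNAJC3 (0.0159) and DNAH14 (0.0421), and lost that of ATP11A (0.0523).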

Other observations

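The tests of a single library, of chromosome copy number, of knockout depth, of the correlation between list members and of NLRC5 were chosen after the results they bear on were seen, as were the name families and the genes named here outside the rule.

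Some changed genes outside the lists were picked after their values were seen, for what they are known to do in neurons, and their number was not tested against other genes. RELN, a secreted guidance protein, rose from 42.5 ± 9.4 to 153 ± 29.2 CPM (SD, n = 3 each, log2 fold change 1.84, SE 0.18, edgeR adjusted p = 0.000154). The microtubule protein MAP1A rose by 1.46 (SE 0.13), the vesicle priming factor CADPS by 1.67 (SE 0.17), SYT11 by 1.29 (SE 0.14) and the guidance receptor ROBO2 by 1.27 (SE 0.16). The sodium channel genes SCN2A, SCN3A and SCN9A rose by 3.00 (SE 0.39), 2.48 (SE 0.39) and 1.14 (SE 0.15). Not all such genes rose: GABRB2, a GABA receptor subunit, had a log2 fold change of -2.74 (SE 0.36). Over 299 families of genes sharing a name stem, tested in each direction, none passed Fisher's exact test after adjustment, and 2 came nearest. Of 507 ZNF genes 30 fell, 5.92% against 2.86% elsewhere (Fisher's exact p = 0.000249, adjusted p = 0.149), and 3 of 12 SCN genes rose (Fisher's exact p = 0.000677, adjusted p = 0.202).

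Class I antigen presentation was looked at because NLRC5, a regulator that switches on class I genes, fell from 20 ± 5.75 to 3.42 ± 0.804 CPM (log2 fold change -2.55, SE 0.25, edgeR adjusted p = 0.000125), along with HLA-B and PSMB8. NLRC5 lies on the far side of chromosome 16, and with chromosome medians removed its log2 fold change was -2.28 (edgeR adjusted p = 0.0025). The hypothesis was that the lower NLRC5 may lower its other targets. Of 8 other listed targets 7 were tested and 6 had a negative log2 fold change, but 4 had an unadjusted p under 0.05 and 0 passed edgeR's adjusted threshold. PSMB9 stood at -0.88 (SE 0.28, edgeR adjusted p = 0.122) and TAP1 at -0.30 (SE 0.12, 0.225), while B2M was at -0.05 (SE 0.17) and HLA-F at 0.58 (SE 0.31). The 4 genes fall short of the 6 asked for, so the hypothesis stays open. It was known beforehand that these targets were not among the called genes.

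Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 756 changed genes and the highest of the others 2. It was the 1 split with a count as high, but 10 splits are too few for a share under 0.05. For lists the real split called 9 and the highest of the others 17, and 4 of the 10 splits called at least as many as the real one. The number of lists called thus did not set the real split apart from splits that mixed the genotypes. Here too 10 splits are too few for a share under 0.05.

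Chromosome 13, chromosome 14 and the far side of chromosome 16 were lower in the knockout. The length and GC composition of transcripts does not account for it, since at least 96.4% of each shift was left with those trends removed, nor does a single library, since at least 93.2% was left without any 1 of the 6. A difference in chromosome copy number between the cell populations is a candidate explanation, as the shift ran along each part: with its genes cut by position into 4 groups of about equal size, each group had at least 75% of the shift of its part. The parts were picked from these data. The difference could be a gain in part of the wildtype cells or a loss in part of the knockout cells, and RNA alone does not tell which. A loss would leave no copy where a chromosome is present in a single copy, as most are in the HAP1 line. The ploidy of these 6 libraries' cells was not measured, so this does not decide between a gain and a loss. Whether it followed from the loss of DEGS1, was carried by the line before, or arose while the knockout cells were made and grown was not tested.

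Far more genes were over 8-fold lower than over 8-fold higher in the knockout, 79 against 10. Of the 79, which include DEGS1, 34 had a mean of at least 5 CPM in wildtype, and the rest stood lower there. Deleted stretches that remove neighbouring genes are argued against for the set as a whole, since the nearest tested genes on either side had a median log2 fold change of -0.092. They stay open for 8 genes that form 4 neighbouring pairs (TCEAL8 and TCEAL9, ZNF676 and ZNF729, BCHE and SLITRK3, CWF19L1 and PHBP9), and for genes whose called neighbour fell less. Such neighbours included SCGB3A2 beside SPINK5 (log2 fold change -2.96) and SLC25A27 beside CYP39A1 (-2.47). Called neighbours that rose were PDE3A beside SLCO1B3 (2.52) and NR2F1 beside CCT7P2 (0.756). Of the 152 neighbours 18 changed, where 4.46% of all tested genes did. A lower depth of the knockout libraries is excluded too, since their total was 106% of the wildtype total. Loss of DEGS1 stays open. So does a difference between the cell populations that existed before the knockout or arose while the knockout cells were made and grown. These were not tested and cannot be told apart here, as the labels name a single knockout.

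The histone, ribosomal protein and respiratory chain lists were called up by camera with its preset correlation. None was called by camera with an estimated correlation (adjusted p = 0.862 each) or by fry in one direction (adjusted p = 0.391, 0.691 and 0.74). With the length and GC trend removed 2 of the 3 were still called, histones (adjusted p = 0.00534) and ribosomal proteins (0.0334) but not the respiratory chain (0.086), so a bias of this kind cannot be told apart from a change for the set as a whole. Members that move together from library to library are a candidate explanation, since the correlation between members left after genotype was 0.601 for histones, 0.94 for ribosomal proteins and 0.654 for the respiratory chain, each above 100% of 1000 random lists of the same size and expression (medians 0.218, 0.421 and 0.211). Such correlation was not particular to them, as 12 of the 37 lists lay above 95% of their random lists. Among these were the integrated stress response (0.446), also called up, and the extracellular matrix (0.176), not called. The called epithelial, blood cell, neuron, lysosome and lipid efflux lists did not reach 95%. The ribosomal protein call was lost without wildtype replicate 1 (0.0731), wildtype replicate 3 (0.314) or knockout replicate 2 (0.113), the respiratory chain was called in 8 of 17 settings (adjusted p up to 0.718), and the histone call was kept in all 17.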
